A study of Mus musculus with 3 samples.

How the data were processed

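Frozen sections of mouse tibialis anterior and extensor digitorum longus muscle were profiled on Visium slides, in which RNA is captured on an array of barcoded spots and counted by unique molecular identifier (UMI) from the 3' end of transcripts. The left sciatic nerve had been clamped to denervate the hindlimb, per the labels' protocols. The 3 sections came from 1 slide and were 1 section of unperturbed muscle, 1 taken 3 days and 1 taken 30 days after the crush. A spot is a small region that can hold several cells of different types, or part of one.

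The deposited matrices hold raw UMI counts per gene and spot, and the authors made them with Space Ranger 1.1.0 and the mm10 genome, per the submitters' processing notes. Seurat is named there too, with its version not given in the sources used here. The matrices held whole-number counts for 32285 features, of which 40 shared a symbol with another feature, and spots outside tissue had been removed before deposit. The number of spots in each matrix equalled the number marked as tissue in the deposited slide alignment. The alignment files used here carry no barcodes, so counts were not joined to positions and no map was drawn. Gene coordinates and transcript lengths were taken from the GENCODE annotation of the same genome build and matched by Ensembl identifier. No doublet caller was run and no cell-type makeup was estimated.

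The sections held 11478715 UMIs in 1230 spots (unperturbed), 9975354 UMIs in 864 spots (3 days) and 9632936 UMIs in 893 spots (30 days). At these depths 3 UMIs correspond to 0.261, 0.301 and 0.311 CPM, in the same order. Counts were summed over the spots of a section and scaled to a common total per section to give CPM, the counts per 1000000 UMIs. Ratios of CPM between sections carry exact 95% conditional binomial (Clopper-Pearson) intervals, and shares carry exact 95% binomial intervals. All intervals cover counting error only. With 1 section per condition there was no test, no p-value and no estimate of the spread between animals, and the animal, the plane of section and the mix of both muscles in a section cannot be told apart from the condition. Genes with at least 200 UMIs over the sections compared were counted as higher or lower when their ratio was at least 2 or at most 0.5.

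The choices in this paragraph were made before the data were examined. Named genes were, for each comparison, the 10 with the largest and the 10 with the smallest ratio by the end of the interval nearest to 1, leaving out predicted genes, pseudogenes and mitochondrial genes. A further 24 genes were always included (Chrna1, Chrnd, Chrng, Chrne, Musk, Myog, Runx1, Gadd45a, Ncam1, Fbxo32, Trim63, Mstn, Myh1, Myh2, Myh4, Myh7, Myh3, Myh8, Amd1, Odc1, Smox, Sat1, Pvalb and Actn3), with up to 4 members of each gene list that had at least 200 UMIs and the largest ratios in either direction. Some genes that this rule names, and a test of free RNA that rests on them and was not settled, are not reported here. There were 18 lists of pathways or complexes and 12 lists of cell type markers. The pathway lists covered the nerve-muscle synapse, the response to denervation, atrophy and ubiquitin ligases, autophagy and lysosome, proteasome, polyamine metabolism, fast contractile, slow contractile and developmental contractile genes, glycolysis, nuclear-encoded respiratory chain subunits, mitochondrially encoded genes, fatty acid metabolism, extracellular matrix, cytosolic ribosomal proteins, immediate early genes, heat shock genes and genes of dividing cells. The marker lists covered macrophages, neutrophils, lymphocytes, fibroblasts, tendon cells, Schwann cells, injured Schwann cells, endothelium, smooth muscle with pericytes, satellite cells, adipocytes and erythrocytes. A list's value was the median log2 ratio of its members with at least 20 UMIs over the 3 sections, computed with 0.5 added to each count. Its percentile among 10000 random lists of the same size matched on mean expression in 20 bins was given as a description of these sections. Members counted as higher or lower had a ratio at least 1.5-fold from 1 and an interval on the same side of 1.

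Within each section, spots with at least 20 UMIs of Myh1, Myh2, Myh4 and Myh7 were ordered by the Myh4 share of these, and the third of spots with the highest and the third with the lowest share were summed (high-Myh4 and low-Myh4 spots). These are ranges of a score, not fibre types. Their ratios of ratios have 95% intervals from the summed inverse counts. For the share of spots with a UMI of a synaptic gene, each spot was thinned at random to 3946 UMIs, the 10th percentile of the shallowest section, which left out 35, 86 and 14 spots in order of time. Each section was clustered alone (scanpy 1.11.5, 2000 most variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.5 with leidenalg 0.10.2 and igraph 0.11.9), and the resulting regions were called by their leading genes.

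The computations were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. edgeR 4.0.16 in R 4.3.3 gave TMM factors only. The alternatives tried were 3 other library scalings (without mitochondrial and hemoglobin genes, median-of-ratios size factors, TMM factors), equal weight per spot, a minimum of 500 UMIs and 250 genes per spot, leaving out the tenth of spots richest in cell type markers, other count filters, and other settings of the split, the thinning and the clustering. A further alternative, only spots with 5000 to 12000 UMIs, was chosen after seeing the data, because depth per spot differed between sections.

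The ratios, list medians, split of spots and thinning were tested on simulated data. Counts were drawn from the section means with 200 genes changed by known folds. In the simulated comparison of 3 days with unperturbed muscle, the interval held the true ratio for 96.0% of 5519 unchanged genes, and none of these lay 2-fold apart. All 44 genes changed 3-fold were found, 17 of 42 changed 2-fold and 1 of 46 changed 1.5-fold. In the comparison of 30 days with unperturbed muscle the interval held the true ratio for 95.5% of 5474 genes, and 45 of 45 genes changed 3-fold and 21 of 47 changed 2-fold were found. In that of 30 days with 3 days it was 95.0% of 5218 genes, with 44 of 44 and 20 of 49 found. The changed genes moved the CPM of unchanged genes by -0.23, -0.10 and -0.014 log2 units in these 3 simulations, since scaling by the total moves with abundant genes. The true ratio of an unchanged gene was taken as its CPM ratio after this shift, not as 1. The shares above thus do not say how often an interval held 1 for an unchanged gene.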

Results

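Gene expression was measured by spatial RNA sequencing in mouse tibialis anterior and extensor digitorum longus, the muscles that lift the foot and toes. Unperturbed muscle was set against muscle taken after a crush of the sciatic nerve, which interrupts the motor supply of these muscles. The data comprised 1 section of unperturbed muscle, 1 section taken 3 days after the crush and 1 section taken 30 days after it. The unperturbed section held 1230 spots with a median of 8502 UMIs and 1621 genes, the 3-day section 864 spots with a median of 8071 UMIs and 1638.5 genes, and the 30-day section 893 spots with a median of 10473 UMIs and 1958 genes. Depth per spot was most uneven at 3 days, where the 25th and 75th percentiles were 5502 and 15826 UMIs, against 6561 and 10846 UMIs in the unperturbed section and 8768 and 12531 UMIs at 30 days. Mitochondrially encoded transcripts took 32.4%, 31.9% and 35.1% of UMIs in order of time, ribosomal protein transcripts 5.99%, 5.84% and 3.85%, hemoglobin transcripts 0.619%, 0.580% and 0.365%, and the markers of other cell types 1.02%, 0.999% and 0.774%. As each condition had 1 section, no difference below has a replicate check, and the ranges in parentheses are 95% counting intervals of a ratio of counts scaled to the section total (CPM).

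The first comparison asked which transcripts differed from unperturbed muscle 3 days after the nerve was crushed. Transcripts of 2 ubiquitin ligases known from muscle atrophy, Fbxo32 and Trim63, were higher in the 3-day section. Fbxo32 (ENSMUSG00000022358, chromosome 15, 58175879 to 58214932, mm10), which encodes the muscle ubiquitin ligase atrogin-1, stood at 218.4 CPM against 99.4 CPM, a ratio of 2.20 (2.04 to 2.36). Trim63 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629), which encodes the ubiquitin ligase MuRF1, had a ratio of 1.70 (1.60 to 1.82). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), a kinase that limits the entry of pyruvate into oxidation, reached 2.91 (2.67 to 3.17), and the muscle carbonic anhydrase Car3 2.53 (2.42 to 2.64). The collagen transcript Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) was lower, at 0.342 (0.322 to 0.363).

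Of 5689 genes with enough UMIs, 14 were at least 2-fold higher and 29 at least 2-fold lower at 3 days. For 4 of the higher and 14 of the lower genes the counting interval lay wholly beyond 2-fold. The median gene had a log2 ratio of 0.12 under scaling by the total, so a log2 ratio of 0.12 marks no difference from the bulk of genes. Median-of-ratios and TMM scaling removed that shift and gave 7 higher and 40 lower genes, and 7 higher and 39 lower genes, so that the higher share went from 32.6% to 14.9% and 15.2%. Other settings turned the balance: weighting every spot equally gave 22 higher and 16 lower genes (57.9% higher), and leaving out the tenth of spots richest in cell type markers gave 20 and 12 (62.5%). Other genes with large ratios were Egr1, an immediate early transcription factor (3.40, 2.54 to 4.60), Mylip at 2.24, the clock gene Arntl at 2.15, Srsf5 at 84.0 against 42.8 CPM, Tacc2 at 1.95 and Apod at 1.94. Small ratios were those of the metallothionein Mt2 (0.213, 0.175 to 0.256), the chemokine Ccl8 at 0.220, haptoglobin (Hp) at 0.224, Nr4a3 at 0.298, the lipid desaturase Scd1 at 0.315, Chac1 at 0.338 and Ifi27l2a at 0.417.

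Among the lists fixed in advance, the atrophy and ubiquitin ligase list had a median log2 ratio of 0.32 at 3 days, at the 99.7th percentile of random lists, with 3 of 16 members higher and 1 lower. Its higher members included Fbxo32 and Trim63, while Cebpd was at 0.653 (0.531 to 0.799). Myostatin (Mstn; ENSMUSG00000026100, chromosome 1, 53061640 to 53068079), which restrains muscle growth, was at 0.763 (0.661 to 0.880). All 18 genes of the fatty acid list had ratios above 1, with a median of 0.33 (100th percentile), and 2 of them, Pdk4 and Ucp3 (1.52, 1.29 to 1.79), were at least 1.5-fold higher. The autophagy and lysosome list had a median of 0.20 with none of its 16 members past 1.5-fold, although Gabarapl1 stood at 1.44 and Map1lc3b at 1.38. The extracellular matrix list was lower, with a median of -0.48 (0th percentile) and 9 of 20 members lower, among them Col1a1 at 0.461, Col1a2 at 0.481 and fibronectin (Fn1) at 0.485. Lower values were also found for the markers of macrophages (median -0.75, 8 of 12 lower, C1qa at 0.529), adipocytes (-1.44, 5 of 6 lower, Cfd at 28.9 against 57.8 CPM), tendon cells (-0.57, 4 of 10 lower, Fmod at 0.559) and fibroblasts (-0.24, 0 of 10 past 1.5-fold). The summed macrophage markers were lower in high-Myh4 spots only, at 364.7 against 590.2 CPM in the unperturbed section. In low-Myh4 spots they stood at 145.8 against 122.6 CPM. Neutrophil markers had a median of -1.52, with 2 of 3 measured genes lower and 1 higher, but all UMIs of S100a8 in the unperturbed section lay in 10 spots. Schwann cell markers were higher, with a median of 0.66 (100th percentile) and 5 of 10 members higher, and so were the endothelial markers Cdh5 at 1.65 and Kdr at 1.61 within a list median of 0.24.

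For the other lists the median log2 ratios at 3 days were 0.081 for the proteasome, 0.19 for polyamine metabolism, 0.11 for glycolysis, 0.024 for the nuclear-encoded respiratory chain, -0.068 for mitochondrially encoded genes and -0.042 for ribosomal proteins. Heat shock genes had a median of 0.12 and immediate early genes 0.18, the latter with 4 of 11 members higher, including Egr1. Medians were -0.0091 for fast contractile genes, 0.049 for slow contractile genes and -0.23 for genes of dividing cells. The developmental contractile list was mixed, with a median of -0.34 (4.40th percentile) but 2 of 5 members higher and 0 lower by the 1.5-fold rule. The cell type markers of erythrocytes had a median of 0.069, of smooth muscle and pericytes -0.16 (0.38th percentile), of satellite cells -0.077, of lymphocytes 0.082 over 2 measured genes and of injured Schwann cells 0.71 over 3 measured genes. Slow contractile genes included Myh7, the slow myosin heavy chain, at 0.295 (0.171 to 0.487) and Myl2 at 11.6 against 23.3 CPM. In spots with 5000 to 12000 UMIs their ratios were 0.0626 and 0.0345. Few spots carried Myl2, 82 in the unperturbed section and 32 at 3 days. Of the 78 Myh7 UMIs in the unperturbed section, 62 lay in the same region of the clustering below. The counting intervals do not cover where such spots fell. When only spots with 5000 to 12000 UMIs were used, a setting chosen after seeing the data, the median log2 ratio became -0.28 for Schwann markers and -0.057 for the fatty acid list, that of autophagy and lysosome genes -0.0023, Mstn turned to 0.088, and the ratio of Apod was 1.29. Proteasome, glycolysis and heat shock genes turned to medians just below 0 under median-of-ratios and TMM scaling (-0.050, -0.023 and -0.011 under the former). With every spot weighted equally the medians of Schwann, tendon cell and fibroblast markers became -0.014, 0.081 and 0.11. The smooth muscle and pericyte median turned to 0.0016 under that setting and to 0.27 in spots with 5000 to 12000 UMIs. It was 0.49 without the tenth of spots richest in markers and 0.074 with members of at least 200 UMIs only.

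Transcripts of the nerve-muscle synapse, many of which are under the control of the motor nerve, were followed gene by gene. The synapse list had a median log2 ratio of 0.10 at 3 days (38.3th percentile), with 0 of 14 members higher and 1 lower. Chrna1 (ENSMUSG00000027107, chromosome 2, 73563215 to 73580338), the alpha subunit of the muscle acetylcholine receptor, was counted 156 times in the unperturbed and 113 times in the 3-day section, a ratio of 0.834 (0.648 to 1.07). The adult epsilon subunit Chrne was at 0.892 (0.693 to 1.15), the delta subunit Chrnd at 1.69 (0.837 to 3.50) on 15 and 22 UMIs, and Chrnb1 at 1.36 (1.05 to 1.77). In spots with 5000 to 12000 UMIs Chrnb1 turned to a log2 ratio of -0.039 and Chrnd to a ratio of 0.358, on still fewer UMIs. The fetal gamma subunit Chrng had 2, 0 and 2 UMIs in order of time, too few for a ratio. The denervation list had a median of 0.20 (71.7th percentile), with 3 of 13 members higher and 1 lower, the higher ones including the growth arrest gene Gadd45a at 1.97 (1.62 to 2.40) and the myogenic factor Myod1 at 1.80 (1.51 to 2.16). The myogenic factor Myog had 19 UMIs in both sections (1.15, 0.577 to 2.30), Runx1 was at 1.21 (0.623 to 2.35), Musk at 1.58 (0.580 to 4.53) on 8 and 11 UMIs, and Ncam1 at 0.854 (0.475 to 1.51). For Chrnd, Myog, Runx1 and Musk a 2-fold difference was not excluded at this depth.

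**Figure D1:**
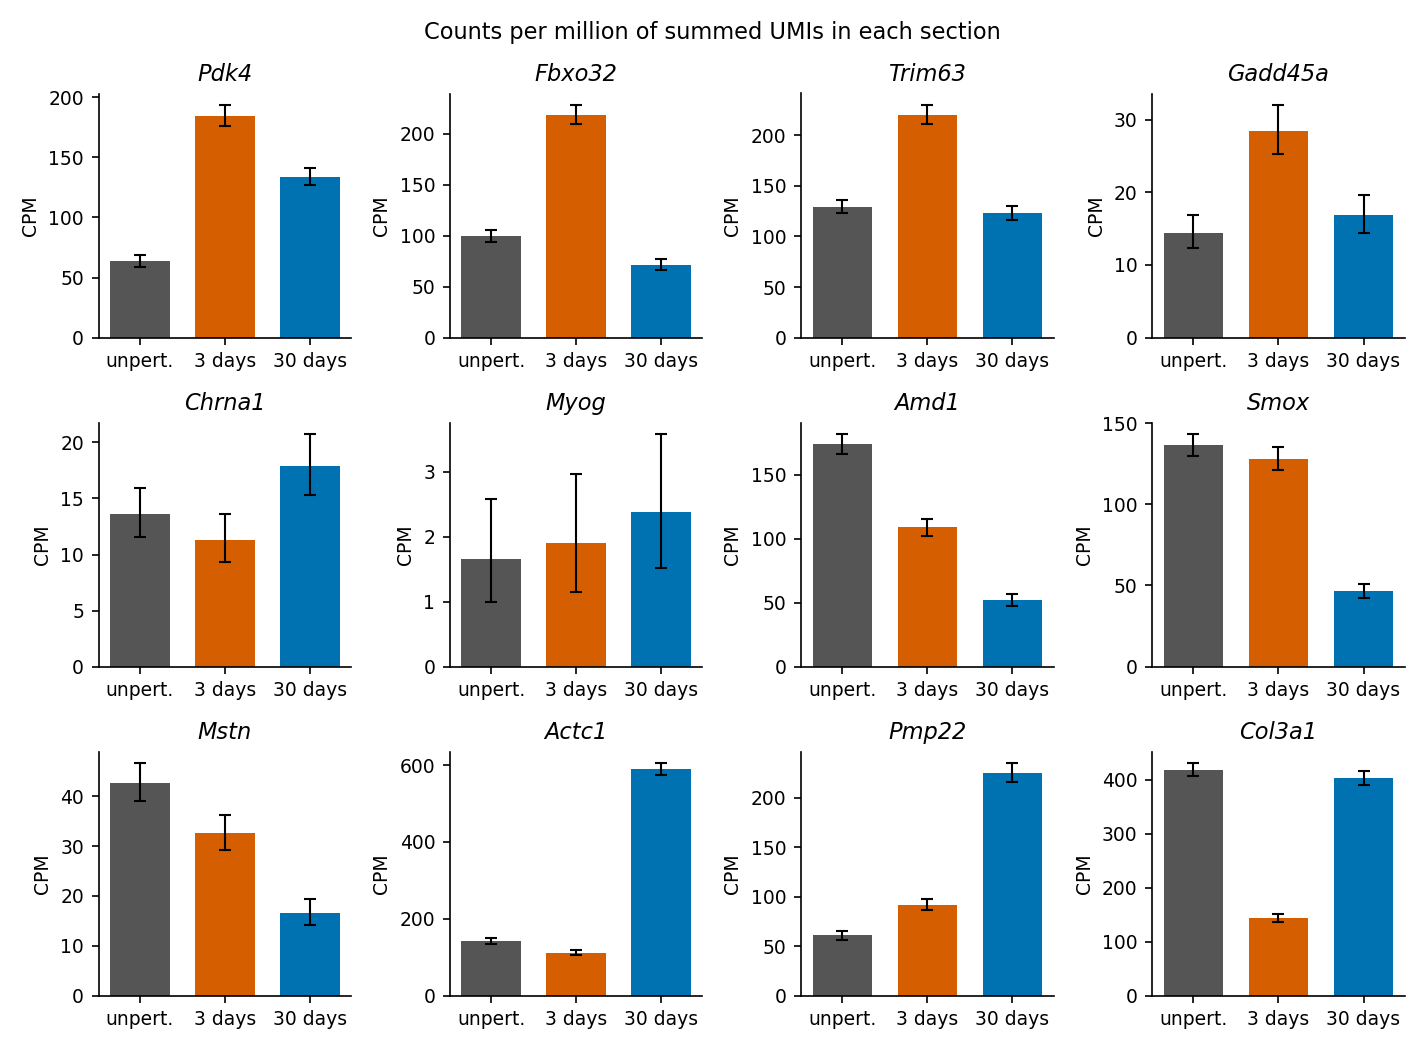
CPM of 12 named genes in each section, with bars for 95% counting intervals and 1 section per condition. Fbxo32 lay at 99.4, 218.4 and 71.2 CPM in order of time and Amd1 at 173.8, 108.8 and 51.8 CPM. Within high-Myh4 and low-Myh4 spots the 3-day ratio of Amd1 to unperturbed was nearer to 1, at 0.845 and 0.857.

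The second comparison asked which transcripts differed from unperturbed muscle 30 days after the crush. Myelin transcripts were among those with the largest ratios: Prx was at 4.93 (3.54 to 6.98), Mal at 18.5 against 4.62 CPM, Pmp22 at 3.70 and Mbp at 3.31. Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548), the cardiac actin of immature muscle, reached 4.15 (3.92 to 4.38), the imprinted RNA H19 3.37 (3.06 to 3.72), the myosin-binding protein Mybph 3.34 and Apod 3.19. In polyamine metabolism some genes were lower, among them Amd1 (ENSMUSG00000075232, chromosome 10, 40287458 to 40302186), which encodes the synthesis enzyme S-adenosylmethionine decarboxylase, at 0.298 (0.270 to 0.329), and the spermine oxidase Smox (ENSMUSG00000027333, chromosome 2, 131491496 to 131525922), at 0.340 (0.305 to 0.378).

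At 30 days 37 of 5602 genes were at least 2-fold higher and 65 at least 2-fold lower, and the median gene was at 0.042 log2 units. The interval lay wholly beyond 2-fold for 17 of the higher and 35 of the lower genes. Scaling without mitochondrial and hemoglobin genes gave 55 higher and 56 lower genes, moving the higher share from 36.3% to 49.5%. Small ratios were those of Hp (3 UMIs against 200, ratio 0.0179, 0.00366 to 0.0530), Ccl8 at 0.0559, Cfd at 0.0791, Wfdc17 at 0.140, the joint lubricant Prg4 at 0.153, Mt2 at 0.157, Ifi27l2a at 0.185, the chemokine Ccl6 at 0.218 and Chac1 at 0.232. Fbxo32 was lower than in unperturbed muscle, at 0.716 (0.651 to 0.788), Trim63 was at 0.953 (0.882 to 1.03) and Mstn at 0.389 (0.323 to 0.466). Pdk4 was at 2.11 (1.92 to 2.31).

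By list, all 10 Schwann cell markers were at least 1.5-fold higher at 30 days, with a median log2 ratio of 2.28, and the 3 measured markers of injured Schwann cells had a median of 1.56. The developmental contractile list had a median of 1.20 (99.9th percentile) with 4 of 5 members higher, although Myh3 was at 1.19 (0.419 to 3.39) on 9 UMIs in both sections and Myh8 at 2.89 (1.14 to 8.25) on 7 and 17 UMIs. The synapse list had a median of 0.41 (99.7th percentile) with 2 of 14 members higher, and Chrna1 was at 1.31 (1.05 to 1.64), Chrnd at 2.86 (1.53 to 5.62), the esterase Ache at 1.74 (1.36 to 2.24) and Chrnb1 at 1.44 (1.12 to 1.87), while Chrne was at 0.957 (0.744 to 1.23) and Dok7 at 0.732. In the denervation list (median 0.22, 3 of 13 higher and 1 lower) Runx1 was at 2.26 (1.28 to 4.11), Gadd45a at 1.16 (0.931 to 1.45) and Myod1 at 0.752. Polyamine metabolism had a median of 0.037, with 4 of 15 members lower, 1 higher and 10 within 1.5-fold: beside Amd1 and Smox, its near-identical copy Amd2 was at 0.397, the synthesis enzyme Odc1 at 0.609 (0.532 to 0.696) and the antizyme Oaz2, an inhibitor of that enzyme, at 1.99 (1.77 to 2.24). Counts of Amd1 and Amd2 are uncertain as a pair, since reads can be split between such copies. Ribosomal protein genes were lower, with a median of -0.57 (0th percentile), 38 of 84 lower and none higher, for example Rpl35 at 0.465, Rps20 at 0.479 and Rps27 at 0.491.

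The matrix list had a median of 0.18 at 30 days, with 4 of 20 members higher, among them the basement membrane collagen Col4a2 at 1.92 and Postn at 1.83, and 2 lower, among them Lox at 0.429. Immediate early genes had a median of 0.54 with 4 of 11 higher, and the fatty acid list one of 0.27 with 17 of 18 ratios above 1. Macrophage markers stayed below the unperturbed section (-0.77, 7 of 12 lower), as did those of tendon cells (-1.04, 7 of 10 lower) and adipocytes (-3.58, 5 of 6 lower). Summed, the macrophage markers stood at 237.6 against 590.2 CPM in high-Myh4 spots, but at 146.2 against 122.6 CPM in low-Myh4 spots. The lower value thus did not hold across each section. Erythrocyte markers were lower at 30 days (-0.68, 4 of 6 lower), while their 3-day median was 0.069 with 0 of 6 lower. Neutrophil markers had a median of -4.85 with 2 of 3 measured genes lower and 1 higher. Few spots carried the unperturbed value: the 120 UMIs of S100a8 lay in 10 spots, 57 of them in 1 spot. Lymphocyte markers had a median of 1.24 over 2 genes, with the immunoglobulin chain Ighm at 2.90 (2.39 to 3.53). Fibroblast markers had a median of -0.14, with Col15a1 at 2.42 and Pi16 at 0.526, and endothelial markers one of 0.20, with Tie1 at 1.98. The other medians were 0.0038 for atrophy and ubiquitin ligases, -0.040 for autophagy and lysosome, -0.15 for the proteasome, 0.073 for fast contractile genes, 0.14 for slow contractile genes, 0.073 for glycolysis and -0.0020 for the nuclear-encoded respiratory chain. They were 0.038 for mitochondrially encoded genes, -0.039 for heat shock genes, 0.14 for genes of dividing cells, 0.030 for smooth muscle and pericytes and 0.15 for satellite cells.

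**Figure D2:**
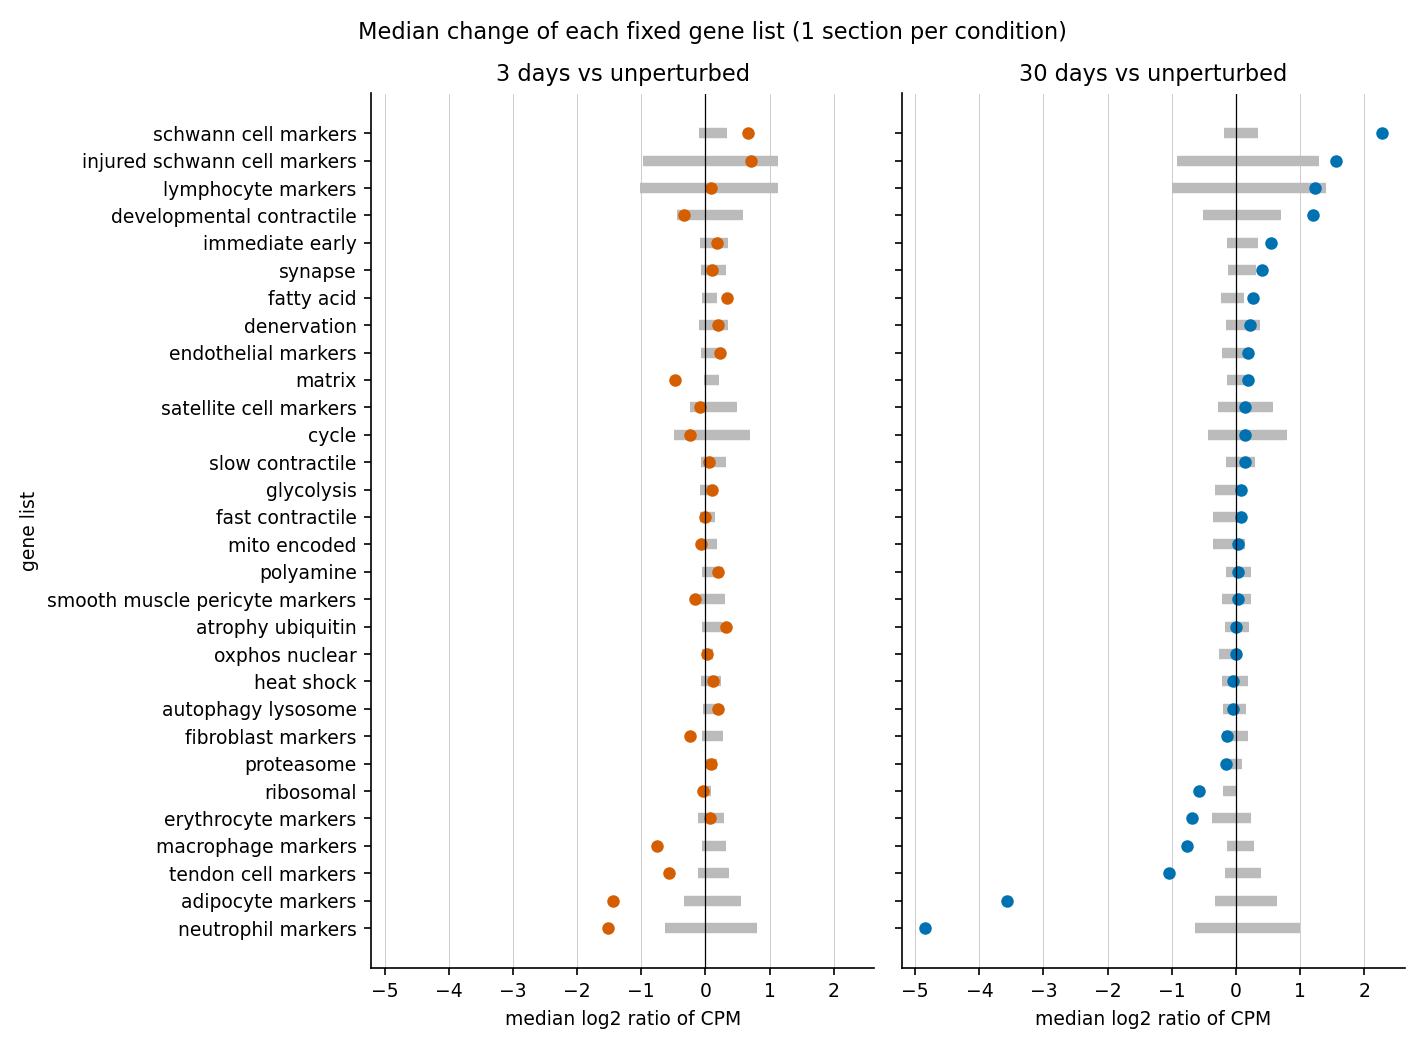
Median log2 ratio of each gene list at 3 and 30 days against the unperturbed section, drawn over the central 95% of random lists matched on expression. Schwann cell markers lay at 0.66 and 2.28, and ribosomal proteins at -0.042 and -0.57.

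The third comparison set the 30-day section against the 3-day section. Transcripts of the same ubiquitin ligases were lower at 30 days, Fbxo32 at 0.326 (0.299 to 0.355) and Trim63 at 0.559 (0.520 to 0.600), and so was Smox at 0.361 (0.324 to 0.403). Actc1 was at 5.25 (4.92 to 5.60), Mybph at 3.61, the matrix protein Spp1 at 3.17, the clock gene Dbp at 2.97, Col3a1 at 2.82 (2.65 to 3.00), Prkg1 at 2.79, the transferrin receptor Tfrc at 2.76 and H19 at 2.63. Counts at least 2-fold apart were 33 higher and 50 lower of 5509 genes, 19 of each with the interval wholly beyond 2-fold, and the median gene was at -0.090. Median-of-ratios scaling gave 45 higher and 36 lower genes, as did scaling without mitochondrial and hemoglobin genes, which moved the higher share from 39.8% to 55.6%. Cfd at 0.158, Ces1d at 0.288, Cntfr at 0.294, Amy1 at 0.317, Rbpms at 0.322, Fkbp5 at 0.340, Fbln1 at 0.349 and Rps27 at 0.445 completed the lower end. Matrix genes were higher, with a median log2 ratio of 0.73, 16 of 20 members higher and Lox lower at 0.543, and 9 of 10 Schwann markers were higher (median 1.44). The developmental contractile list had a median of 1.98, with 2 of 5 members higher and 1 lower. The synapse list had a median of 0.24 with 4 of 14 higher (Chrna1 at 1.58, 1.24 to 2.02). The denervation list had one of 0.35 with 5 higher and 2 lower (Myod1 at 0.417), the atrophy list -0.29 with 4 lower and the ribosomal list -0.52 with 28 of 84 lower. In spots with 5000 to 12000 UMIs the log2 ratio of Cfd turned to 1.68, that of Lox to 0.90 and that of Pdk4, whose ratio was 0.725 over all spots, to 0.051.

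The adult myosin heavy chains were compared as shares of their summed UMIs, which scaling does not affect. Myh4, the chain of the fastest fibres, made up 78.1% (77.9 to 78.3) in the unperturbed section, 74.2% (74.0 to 74.4) at 3 days and 69.7% (69.5 to 69.9) at 30 days. Myh1 took 20.3%, 24.2% and 28.8% in the same order, Myh2 1.52%, 1.58% and 1.51%, and the slow chain Myh7 0.0414%, 0.0112% and 0.0121%. The place of the 3-day section depended on how spots were weighted: its Myh4 share was 81.5% as a mean over spots and 86.4% in spots with 5000 to 12000 UMIs, above the 76.0% and 77.7% of the unperturbed section, while the 30-day shares of 65.1% and 71.4% stayed the lowest. In CPM, Myh1 was at 1.30 (1.29 to 1.32) and 1.63 (1.61 to 1.65) times its unperturbed level at 3 and 30 days, and the 3-day difference turned to a log2 ratio of -0.52 in spots with 5000 to 12000 UMIs. Myh4 was at 1.04 and 1.02 times its unperturbed level, values that fell on the other side of 1 under median-of-ratios and TMM scaling.

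Differences were compared between spots with a high and a low Myh4 share. Each section had its own bounds, so low-Myh4 spots had a mean Myh4 share of 54.2%, 59.3% and 33.8% in order of time and high-Myh4 spots one of 93.4%, 98.3% and 90.7%. Ratios between sections compared unlike spots to that extent. Amd1 was concentrated in high-Myh4 spots in all 3 sections, at 317 against 70.3 CPM in the unperturbed section, 268 against 60.2 CPM at 3 days and 87.5 against 27.7 CPM at 30 days. Its 30-day ratio was 0.276 in high-Myh4 and 0.395 in low-Myh4 spots, a ratio of ratios of 0.699 (0.533 to 0.916). At 3 days it was 0.845 in high-Myh4 and 0.857 in low-Myh4 spots, closer to 1 than the 0.626 of the whole section, and in spots with 5000 to 12000 UMIs it was 0.943. The sum over the 3-day section drew more on spots poor in Amd1. Low-Myh4 spots held 5267504 of its 9975354 UMIs, against 4014167 of 11478715 UMIs in the unperturbed section. The ratio of 0.626 thus mixes this weighting with any difference within spots. The 3-day ratio of ratios, 0.986 (0.810 to 1.20), became 0.581 in spots of that depth. An equal 3-day ratio in both kinds of spots thus depended on which spots were kept. Depth and tissue cannot be told apart here, since the restriction moved the 3-day Myh4 share from 74.2% to 86.4%. Smox was at 0.343 and 0.340 in high-Myh4 and low-Myh4 spots at 30 days, and Fbxo32 at 2.61 and 2.66 at 3 days. Pdk4 at 3 days was at 1.48 in high-Myh4 and 3.17 in low-Myh4 spots (ratio of ratios 0.466, 0.361 to 0.601), and Actc1 at 0.417 and 1.24 (0.335, 0.265 to 0.423). Chrna1 at 30 days was at 2.42 in high-Myh4 and 0.789 in low-Myh4 spots (ratio of ratios 3.07, 1.70 to 5.53). This was not shared by Chrne (1.12, 0.586 to 2.14), and Chrnd (1.33, 0.319 to 5.52) had too few UMIs to tell. The Chrna1 value rested on 29 and 62 UMIs in the unperturbed section and 66 and 40 at 30 days. These lay in few spots, and the interval does not cover where such spots fell.

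At 30 days 74 of 3486 genes had a ratio at least 1.5-fold greater in high-Myh4 spots and 343 in low-Myh4 spots. In simulated counts 121 of 3599 unchanged genes reached this in both directions together. The simulation held counting error only, without clustering of transcripts in spots or differences between spots. An excess over it cannot be ascribed to the crush. Synpo2l (2.23), Atp1b2 (2.28), Ufsp1 (2.37), Dusp1 (2.11) and Ldhb (1.89) had the largest ratios of ratios, and Apod (0.133), Myh11 (0.173), Mbp (0.187), Acta2 (0.198) and Igfbp6 (0.225) the smallest, the latter including genes of myelin and of vessel walls. At 3 days the numbers were 128 and 322 of 2321 genes, with 34 of 2045 unchanged genes in a simulation of the same kind. Taf1d (2.93), Smim27 (2.02), Slirp (1.48 in high-Myh4 and 0.741 in low-Myh4 spots), Hba-a1 (1.93) and Rps29 (1.73) lay at one end. Fmod (0.220), Apoe (0.246), Apod (0.313), Srl (0.325) and Ctsd (0.342) lay at the other. The 3-day split was tied to depth, since high-Myh4 spots had a median of 5268 UMIs there and low-Myh4 spots 17016, against 7194 and 9511 in the unperturbed section and 9927 and 10955.5 at 30 days. In spots with 5000 to 12000 UMIs the 3-day numbers were 44 and 47.

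**Figure D3:**
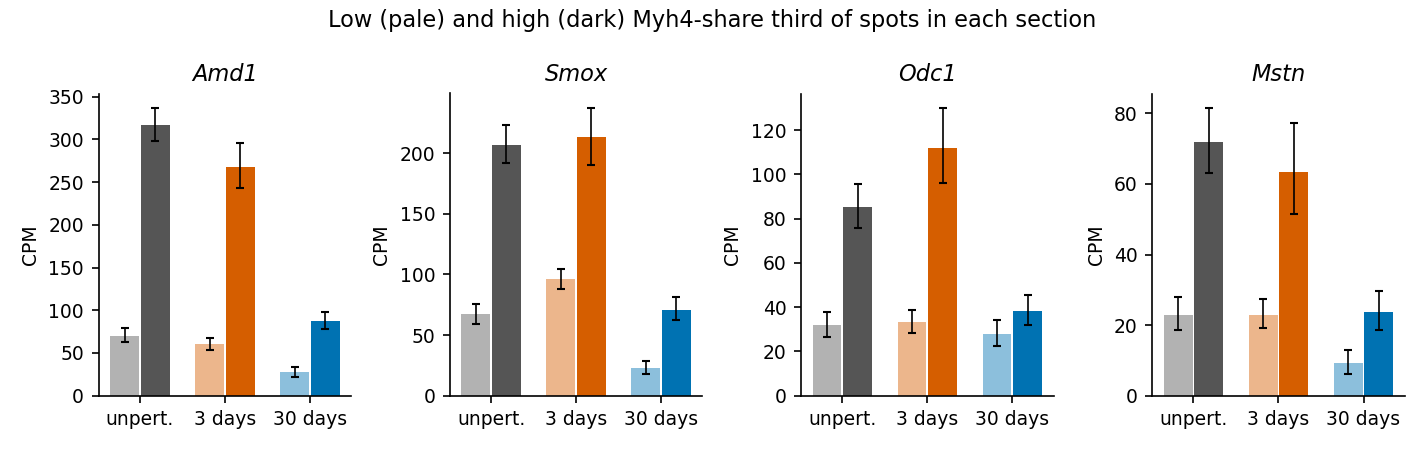
CPM of Amd1, Smox, Odc1 and Mstn in low-Myh4 (pale) and high-Myh4 (dark) spots of each section, with bars for 95% counting intervals. Amd1 lay higher in high-Myh4 spots of all 3 sections, at 317, 268 and 87.5 CPM, than in low-Myh4 spots.

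Transcripts of the receptor subunits Chrna1 and Chrne were concentrated in few spots. After thinning to 3946 UMIs, Chrna1 was detected in 4.27% (3.19 to 5.57) of unperturbed spots, 3.34% (2.19 to 4.86) at 3 days and 6.03% (4.55 to 7.81) at 30 days, and without thinning in 8.21%, 7.18% and 12.1%. Chrne was detected in 3.60%, 2.70% and 4.32% of thinned spots. Chrnd was detected in 0.418% (0.136 to 0.974), 0.514% (0.140 to 1.31) and 1.14% (0.547 to 2.08), Myog in 6 of 1195, 7 of 778 and 11 of 879 spots and Musk in 0.167%, 0.257% and 0.569%, all with overlapping intervals. Chrng was detected in 1 of 1195 thinned spots of the unperturbed section and in none later, although without thinning it was found in 2 spots at 30 days. For Chrna1 the squared coefficient of variation beyond Poisson noise was 7.34, 7.06 and 5.48, against 0.847, 0.607 and 0.839 for Amd1. The postsynaptic genes Rapsn (0.189, 1.08 and 1.14) and Dok7 (0.317, 0.0752 and 1.01) were spread more evenly than Chrna1.

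Clustering each section alone gave 5 regions in the unperturbed section, 3 at 3 days and 5 at 30 days. In the unperturbed section they were led by 1700001O22Rik, F830016B08Rik, Cited4, Amd1 and Amd2 (452 spots), by S100a8, S100a9, Myh7, Myl3 and Myl2 (427 spots, although the S100a8 UMIs of the whole section lay in 10 spots), by Cnn1, Cytl1, Wif1, Col12a1 and Ccl21a (165 spots), by B230312C02Rik, Ube2v2, AY036118, Lyrm2 and Snhg6 (132 spots) and by Mbp, Chrne, Sfrp5 and Chrna1 (54 spots). At 3 days they were led by F830016B08Rik, 1700001O22Rik, Ctxn3, Amd1 and B230312C02Rik (418 spots), by Myl3, Myh2, Myoz2, Slc15a5 and Ankrd2 (228 spots) and by Cfd, S100b, Mal, Prx and Ccl21a (218 spots). At 30 days they were led by Myl3, BC048679, Ankrd2, Gm15543 and Alas2 (288 spots), by Wdr70, Atxn1, Slc47a1, Rbfox2 and Tomm40 (243 spots), by Mybph, Amd2, Prkag3, B230312C02Rik and Gamt (201 spots), by Pmp2, Spp1, Fxyd3 and S100b (141 spots) and by Fmod, Cilp, Prelp, Myoc and Col1a2 (20 spots). Since the leading genes differ between sections, the sizes of regions were not compared.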

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

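The tests of scaling, depth and swapped labels described in this part were chosen after seeing the results, and those of few spots and transcript length before.

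Of 72 genes named at both times by the rules set beforehand, 5 lay on opposite sides of the unperturbed section at 3 and at 30 days, at least 0.32 log2 units from it each time and with both counting intervals off 1. These differences were not tested, since each time point had 1 section, and genes outside the 72 behaved alike, such as Dbp (0.526 and 1.56), which was picked after its values were seen. Fbxo32 was at 2.20 at 3 days and 0.716 at 30 days, the later ratio being 0.326 of the earlier. Myod1 was at 1.80 and 0.752 (0.417 of the earlier), the phosphorylase kinase subunit Phka1 at 1.41 and 0.764 (0.54) and the heat shock gene Hsph1 at 1.48 and 0.662 (0.447). Actc1 went the other way, at 0.790 and 4.15, a factor of 5.25, and its 3-day ratio was 0.417 in high-Myh4 and 1.24 in low-Myh4 spots.

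The summed transcripts of receptor subunits (Chrna1, Chrnd and Chrng), Musk, Myog, Runx1 and Ncam1 were not higher at 3 days, with 251 UMIs in the unperturbed and 209 in the 3-day section, while with Chrne and Gadd45a added the ratio was 1.24 at 3 days and 1.28 at 30 days, and the subunit Chrnb1, not in the sum, was at 1.36. Too few UMIs to see a 2-fold rise cannot be told apart from a true lack of difference: the summed ratio of 0.958 had an upper end of 1.156, but the genes were picked after their values were seen, Chrna1 gave 156 of the 251 UMIs, and 5 of the 7 genes had upper ends above 2. A swap of the 3-day label with the 30-day label cannot be told apart from it either, since the sum at 30 days was 1.61 times that at 3 days (upper end 1.925), higher but short of 2-fold. Fbxo32 (2.20 and 0.716), Trim63 (1.70 and 0.953) and Gadd45a (1.97 and 1.16) were higher in the section labelled 3 days than in that labelled 30 days, the order of an early atrophy response, but no test of the labels was set on them. A single wrong label stays open, and so does the biology of this one section, such as its muscle, its animal or how completely it was denervated, which may account for the pattern but was not tested.

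Schwann cell markers were 4.58 times as abundant at 30 days as in the unperturbed section. An excess confined to the 5% of spots richest in these markers was excluded as the whole cause. The ratio was 3.86 (3.54 to 4.21) without those spots. Those spots held 64.6% of Schwann UMIs in the unperturbed section and 70.0% at 30 days. They numbered 45 at 30 days, while the region led by Pmp2, Spp1, Fxyd3 and S100b held 141 spots. This cut thus cannot exclude a nerve that covers more spots. Without the richest 20% of spots the ratio was 4.20 (3.67 to 4.81). Leaving spots out cannot exclude a larger nerve whose RNA also reached the other spots. Library scaling was excluded within the 3 scalings tried. They shift all genes alike, by 0.054, -0.062 and -0.086 log2 units, which is too little to remove the difference. The lowest median log2 ratio was 2.19. Free RNA of a nerve spread over the section was not excluded and stays open. Growth of Schwann cells or regrowth of myelin could also lie behind the pattern and remains an untested hypothesis.

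Ribosomal protein genes were lower at 30 days, with a median log2 ratio of -0.57. A loss of short transcripts was excluded as the whole cause, as random lists matched on transcript length reached no lower than -0.1217 at their 2.5th percentile. Nuclear respiratory chain genes of like length (710.5 against 712.75 nucleotides) had a median of -0.0020. Across 5431 other genes the rank correlation of length with the log2 ratio was 0.19, shorter transcripts being somewhat lower, so a contribution of length stays open. Library scaling was excluded too within the same 3 scalings, whose shifts of all genes were likewise too small. The highest median was -0.5139. Lower ribosome production in muscle 30 days after the crush might explain it, but no biological explanation was tested. Whether the muscle was still denervated at that time is not given in the sources used here. A difference in tissue makeup or in the handling of this section stays open.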

How the results depend on the processing

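No paired analysis was possible because each condition had 1 section, so no section could be left out in turn either. Of 2579 values of the 369 named-gene ratios under the alternatives, 1903 stayed within counting error, 618 moved in the same direction or were not called, and 58 turned direction. Of 476 values of 60 list medians the numbers were 343, 106 and 27. Every value printed here is one that turned direction, or a main result that moved beyond counting error or, for counts, beyond 1.5 times. Unless stated, the cause was not tested. The minimum of 500 UMIs and 250 genes kept 1227, 864 and 892 spots and moved none of them. The alternatives were chosen before the data were examined, except the restriction to spots with 5000 to 12000 UMIs (921, 398 and 594 spots), which was chosen after seeing the data. Depth limits genes such as Chrnd, Musk and Myog, for which differences of 2-fold lay inside the counting intervals at 3 days.

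The number of genes counted depends by construction on the minimum of UMIs. With 50 UMIs, 105 genes were at least 2-fold higher and 99 lower at 3 days, 241 and 157 at 30 days, and 163 and 137 at 30 days against 3 days. With 1 UMI these numbers were 2037 and 1739, 2350 and 1750, and 2225 and 1731. Asking that the counting interval lie beyond 2-fold left 4 and 14, 17 and 35, and 19 and 19.

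Median-of-ratios factors gave 7 higher genes at 3 days, where the median log2 ratios became 0.18 for atrophy, -0.050 for proteasome, -0.023 for glycolysis, -0.61 for matrix and -0.011 for heat shock genes. At 30 days they gave -0.024 for mitochondrially encoded and -0.63 for ribosomal genes. Myh4 turned to -0.078 at 3 days, -0.028 at 30 days and 0.050 at 30 days against 3 days. TMM factors also gave 7 higher genes at 3 days, with 0.19 for atrophy, -0.042 for proteasome, -0.015 for glycolysis, -0.60 for matrix and -0.0033 for heat shock genes. At 30 days they gave -0.013 for fast contractile, -0.013 for glycolysis, -0.047 for mitochondrially encoded and -0.65 for ribosomal genes. Myh4 turned to -0.069, -0.051 and 0.018 in the 3 comparisons, and at 30 days Pvalb turned to -0.013 and Actn3 to -0.0060. Both factors remove the shift of the median gene at 3 days by construction. Scaling without mitochondrial and hemoglobin genes gave -0.51 for ribosomal genes at 30 days and 0.047 for Myh4 at 30 days against 3 days.

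Weighting every spot equally gave 22 higher and 16 lower genes at 3 days, and 78 and 114 at 30 days against 3 days. At 3 days the medians became -0.14 for synapse, -0.021 for glycolysis, 0.078 for ribosomal and -0.036 for heat shock genes. For markers they became 0.11 (fibroblast), 0.081 (tendon cell), -0.014 (Schwann cell) and 0.0016 (smooth muscle), and the ribosomal median at 30 days was -0.60. Genes that turned at 3 days were Myh1 (-0.093), Myh2 (-0.60), Mybpc1 (-0.10), Serpinf1 (0.00056), Pi16 (0.36) and Mfap5 (0.073). Others were Chad (0.083), Comp (0.28), Thbs4 (0.079), Mbp (-0.029) and Hbb-bt (-0.0073), and Myl3 (0.57) turned at 30 days against 3 days.

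Without the tenth of spots richest in cell type markers, 12 genes were lower at 3 days, the smooth muscle median was 0.49 at 3 days and the Schwann median 1.70 at 30 days. Tagln (0.14), Myh11 (0.13), Hba-a1 (0.025) and Hbb-bs (0.28) turned at 3 days, Tagln (0.12) at 30 days, and Myh4 (0.0072) and Mbp (-0.23) at 30 days against 3 days. With list members of at least 200 UMIs only, the smooth muscle median was 0.074 at 3 days and the Schwann median 1.89 at 30 days.

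Spots with 5000 to 12000 UMIs gave 55 lower genes at 3 days, 43 lower at 30 days and 85 higher at 30 days against 3 days, with fewer genes tested. The restriction also changed which tissue was kept, as the 3-day Myh4 share was 86.4% against 74.2% over all spots. Its effects cannot be ascribed to depth alone. The 3-day medians became -0.10 for synapse, 0.24 for atrophy, -0.0023 for autophagy, -0.11 for glycolysis, 0.017 for mitochondrially encoded and -0.057 for fatty acid genes. They became -1.34 for matrix, 0.13 for ribosomal, -0.18 for heat shock genes, -0.28 for Schwann and 0.27 for smooth muscle markers. At 30 days the ribosomal median was -0.60 and the Schwann median 2.64. Genes that turned at 3 days were Mstn (0.088), Myh1 (-0.52), Myh2 (-1.87), Pvalb (0.018), Chrnb1 (-0.039) and Tnfrsf12a (-0.20). So did Sqstm1 (-0.017), Mybpc1 (-0.27), Pfkm (-0.0046), Hadha (-0.047), Rps7 (0.015), Cryab (-0.063) and Mbp (-0.87). The remaining ones were Pmp22 (-0.46), Tagln (0.17), Myh11 (0.31), Pdgfrb (-0.38), Hba-a1 (0.13) and Hbb-bs (0.13). At 30 days Dok7 turned to 0.16. At 30 days against 3 days Cfd (1.68), Tnfrsf12a (0.10), Myl3 (1.63), Pdk4 (0.051), Lox (0.90), C1qc (0.36), Pi16 (0.51), Fmod (1.66), Myh11 (-0.20) and Acta2 (-0.055) turned.

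The Myh4 share as a mean over spots was 76.0%, 81.5% and 65.1% in order of time, and in spots with 5000 to 12000 UMIs 77.7%, 86.4% and 71.4%. Without the spots richest in markers it was 78.5% in the unperturbed section and 70.2% at 30 days. Splitting spots at the median share gave 73 genes with a 3-day ratio at least 1.5-fold greater in high-Myh4 spots, and the bounds of the unperturbed section gave 511 in low-Myh4 spots. In spots with 5000 to 12000 UMIs the numbers were 44 and 47 of 1305 genes. Spots with Chrna1 made up 5.85%, 5.25% and 7.92% after thinning to the 25th percentile of depth and 8.21%, 7.18% and 12.1% without thinning. Leiden resolution 0.3 gave 3 regions in the unperturbed section, and resolution 1.0 gave 10, 7 and 8 regions in order of time.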

Other observations

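The genes in this part were chosen after their values were seen, and none of their differences was tested.

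The MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1, which serve antigen presentation, were higher at 30 days. Over the whole section the macrophage markers were lower at that time. The lymphocyte markers had a median log2 ratio of 1.24 over 2 genes, with Ighm at 2.90. Cd74 was at 2.25 (2.02 to 2.52), H2-Eb1 at 1.72 and H2-Ab1 at 1.65 times the unperturbed level, against 1.17, 0.980 and 0.981 at 3 days, and H2-Aa stood at 36.7, 31.1 and 71.8 CPM in order of time. The imprinted genes H19, Meg3, Peg3 and Cdkn1c were highest at 30 days too: H19 stood at 49.3, 63.4 and 166.4 CPM in order of time, and the 30-day ratios of Meg3, Peg3 and Cdkn1c were 2.49 (1.93 to 3.23), 1.95 (1.48 to 2.60) and 1.75 (1.42 to 2.16).

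The metallothioneins Mt1 and Mt2 and the acute phase gene Lcn2 were highest in the unperturbed section. Mt1 stood at 107.6, 59.4 and 48.2 CPM in order of time, Mt2 at 62.7, 13.3 and 9.86 CPM, and Lcn2 was counted 26, 6 and 2 times. Fkbp5, Sgk1 and Tsc22d3, which respond to glucocorticoids, were lowest at 30 days, at 0.391 (0.287 to 0.526), 0.647 and 0.675 of the unperturbed level, while Pdk4 and Per1, which respond to them too, were at 2.11 and 1.32. Of the circadian clock genes looked at, Arntl was at 2.15, Cry1 at 1.69 and Nr1d1 at 1.52 at 3 days, and Dbp at 0.526, Per1 at 0.514 and Per2 at 0.493. Nfil3 (1.23), Clock (1.17), Tef (1.09), Nr1d2 (0.959), Hlf (0.948) and Per3 (0.854) lay nearer to 1, and Ciart was counted 11 and 4 times. At 30 days Dbp was at 1.56, Nfil3 at 0.553 and Per2 at 0.477. The hour of tissue collection is not given in the sources used here.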
